A study of Arabidopsis thaliana with 12 samples.

How the data were processed

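The series measured mRNA in whole roots of Arabidopsis thaliana seedlings by RNA sequencing. Per the labels' protocols, the seedlings were 10 days old. Sets of 12 seedlings were then shaken for 1 h in liquid medium with 5 µM benzyladenine (BA), a synthetic cytokinin, or with 0.01% of a 5 N NaOH solution as vehicle, and the roots were cut off and frozen. Libraries came from a stranded mRNA kit with bead capture. The 12 libraries form 4 groups of 3: wild type (WT, accession Col-0) and the quintuple mutant bpc1,2,3,4,6 (bpc), each with vehicle or BA. The groups and the replicate numbers were taken from the sample titles. The labels do not say that the 3 libraries of a group came from separate growths, so the p-values measure only the spread between these samples, which may be technical.

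Per the submitters' processing notes, the authors' tools were FastQC, TopHat2 2.0.11, Bowtie 1.1.0, SAMtools 0.1.18, featureCounts and edgeR 3.0, and the genome build was TAIR10; whether counting used strand is not given in the sources used here. The authors deposited RPKM values (reads scaled by the length of the gene and the read total of the library) for 33602 genes in all 12 libraries, of which 25442 were above 0 in at least 1 library. They also deposited 3 comparison tables of 19706 genes each. Per the file headers, these tables hold log2 fold changes, mean log2 CPM, likelihood-ratio scores and p-values with FDR values from an edgeR fit.

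Read counts were not among the files used, so the depth was read from the steps of the RPKM values. Of 4775 low genes, 3787 (79.3%) had values that were whole multiples of a shared step within 0.0001 of that step. The divisors implied by the steps and the gene lengths, taken from 1235 genes that gave the same value within 100 reads, ran from 9427912 to 13951019 reads per library. At 1 kb, a single read was worth 71.7 to 106.1 thousandths of an RPKM, so genes under about 1 RPKM rest on few reads. The divisor of WT BA replicate 1, 11653485 reads, was identical to that of WT vehicle replicate 2. The length-weighted RPKM sum of that library was 86.5% of the median, against 99.8% to 100.2% in the other 11. Its values were used as deposited, and all comparisons were repeated with that library rescaled to its own total.

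Tests used R 4.3.3 and limma 3.58.1 on log2(RPKM + 0.5), for 20776 genes with at least 0.5 RPKM in at least 3 of the 12 libraries. The fit had 1 coefficient per group and an intensity trend, with 8 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes on this scale understate the change of low genes. The 5 contrasts were BA against vehicle in WT and in bpc, bpc against WT with vehicle and with BA, and the genotype by BA interaction (bpc response minus WT response). The mean BA effect over both genotypes served to pick genes for comparing response sizes and for 1 test of chance.

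Gene lists were fixed before the data were examined, as were the tests, the alternatives that are not described below as added, and the rule for named genes. The rule took, for each contrast, the 6 largest rises and 6 largest falls among genes past the threshold with non-overlapping groups and a group mean of at least 2 RPKM. It added the BPC family and, for each list, up to 4 members past the threshold with the smallest p, or 2 members with values only where none passed. The 29 lists held 414 members, of which 1 was left out because its symbol contradicted its locus, 344 were measured and 69 were not kept by the filter. The lists were the BPC family, type-A response regulators, cytokinin perception and relay, cytokinin response factors, cytokinin breakdown and conjugation, cytokinin biosynthesis, CC-type glutaredoxins, Aux/IAA auxin-response repressors, auxin transport carriers, ethylene synthesis and signalling, gibberellin metabolism, abscisic acid response, jasmonate and wound response, defence and immune response, homeotic floral and KNOX regulators, embryo and seed storage programme, Polycomb components, nutrient uptake transporters, iron-deficiency response, hypoxia response, heat-shock proteins, flavonoid pathway, photosynthesis as a marker of shoot tissue, root hair cells, endodermis, xylem, phloem, root cap and stem cell niche, and mitotic cell cycle. The embryo and seed storage programme kept only SESA4 (AT4G27170), at 0.988 ± 0.525 RPKM in WT vehicle and 0.753 ± 0.418 in bpc vehicle, so 28 lists were tested. List tests used camera with a preset correlation of 0.01, adjusted over 140 tests (28 lists by 5 contrasts), and were repeated with an estimated correlation and with fry.

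The tests were run on simulated data with known changes over 20776 genes. For the BA response in WT, 31.3%, 68.7% and 93.9% of 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold were recovered, with 9 false calls. Shares were 29.9%, 68.7% and 92.4% for BA in bpc, and 31.3%, 79.1% and 98.5% for bpc against WT with vehicle (11 false calls each). For the interaction they were 1.5%, 44.8% and 89.4%, with 3 false calls. With real libraries that deviate alike, these rates may not hold. A simulated response in bpc of 0.7 times the WT response gave slopes of 0.68 for higher and 0.683 for lower genes. The median standard error of a log2 fold change was 0.16, and 0.23 for the interaction.

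Alternatives chosen before the data were examined were a pseudocount of 0.1 or 1, no filter or a minimum of 2 RPKM, median-of-ratios scaling, quantile normalization, TPM, each contrast fitted on its own 2 groups, robust empirical Bayes, no intensity trend, array weights, a replicate block, and each library left out in turn. Alternatives chosen after seeing the data were WT BA replicate 1 rescaled to its own total, both vehicle libraries numbered 3 left out, and the 2 vehicle groups alone with a replicate block. The same replicate numbers occur in all 4 groups of the labels, which do not say what they share. Deviations from the group means correlated across genes at 0.31, 0.37 and 0.63 between vehicle libraries numbered 1, 2 and 3 of the 2 genotypes. Deviations cancel within each group, so likeness of libraries numbered 3 alone would raise the other correlations. These values thus show a shared deviation for number 3 and cannot show a pairing for 1 and 2. In the other 3 pairs of groups, correlations ran from −0.28 to 0.16.

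Locus identifiers were matched to the TAIR10.1 annotation, in which 32835 identifiers (97.7%) were found, and coordinates below are from that annotation. Reads shared between near-identical copies can be split by the counting, so values of the tandem glutaredoxins GRXS3, GRXS4, GRXS5, GRXS7 and GRXS8, of KIN1, COR15A, VSP1, VSP2, LHCB1.2, LHCB1.3 and of AT4G08410 and AT4G12500 are uncertain, as are those of genes with an antisense partner. The result of 1 gene family, among those grouped by symbol after the data were seen, is not reported here.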

Results

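RNA was sequenced from roots of 10-day-old Arabidopsis seedlings after 1 h with benzyladenine (BA, a synthetic cytokinin) or vehicle. The seedlings were wild type (WT) or, in the 6 libraries labelled bpc1,2,3,4,6 and called bpc here, mutant in BASIC PENTACYSTEINE genes, which encode transcription factors that bind GAGA motifs. Each of the 4 groups held 3 libraries, of 9427912 to 13951019 reads by the steps of the RPKM values. The design asks which root transcripts respond to cytokinin, which differ in bpc, and whether the response differs in bpc. Levels are means in RPKM ± SD (n = 3). Fold changes are log2 ± SE on the log2(RPKM + 0.5) scale, with adjusted p-values from limma for genes and from camera for lists. A value given for a lost call is the log2 fold change, or the median of a list, without that library or under that alternative.

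The BPC genes check the genotype labels. BPC1 (AT2G01930; chromosome 2, 427114 to 428900) had 11.7 ± 1.53 RPKM in WT with vehicle and 16.7 ± 3.01 with BA, against 1.79 ± 0.39 and 1.4 ± 0.406 in bpc. BPC2 (AT1G14685; chromosome 1, 5042240 to 5045556) had 17.1 ± 1.79 RPKM in WT with vehicle and 16 ± 0.823 with BA, against 1.58 ± 0.318 and 1.38 ± 0.115 in bpc. BPC6 (AT5G42520; chromosome 5, 17000259 to 17002607) had 31.9 ± 5.23 RPKM in WT with vehicle and 27.8 ± 3.75 with BA, against 1.32 ± 0.468 and 1.45 ± 1.18 in bpc. The bpc levels were 15.3%, 9.23% and 4.12% of WT with vehicle. Log2 differences with vehicle were −2.42 ± 0.19 (adjusted p = 3.2e-05), −3.09 ± 0.13 (adjusted p = 2e-07) and −4.18 ± 0.32 (adjusted p = 2.5e-05). With BA they were −3.19 ± 0.19 (adjusted p = 2.4e-06), −3.13 ± 0.13 (adjusted p = 1.7e-07) and −4.01 ± 0.32 (adjusted p = 3.1e-05).

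BPC4 (AT2G21240; chromosome 2, 9101277 to 9103141) had 23.4 ± 2.88 RPKM in WT with vehicle and 24.6 ± 1.75 with BA, against 16.3 ± 1.68 and 16.9 ± 0.662 in bpc. It was lower in bpc by log2 −0.5 ± 0.12 (adjusted p = 0.046) with vehicle and −0.52 ± 0.12 (adjusted p = 0.035) with BA. BPC3 (AT1G68120; chromosome 1, 25526296 to 25527105) had 1.38 ± 0.255 RPKM in WT with vehicle and 2.16 ± 0.472 with BA, against 3.16 ± 0.71 and 3.51 ± 0.738 in bpc. BPC3 was thus higher in the libraries labelled as its mutant, by 0.95 ± 0.2 (adjusted p = 0.031) with vehicle, and its difference with BA was 0.59 ± 0.2 (adjusted p = 0.17). The insertion sites are not given in the sources used here, so remaining reads check nothing there. BPC5 (AT4G38910; chromosome 4, 18145188 to 18147080) had 1.9 ± 0.141 RPKM in WT with vehicle and 1.44 ± 0.266 with BA, against 2.45 ± 0.525 and 2.69 ± 0.2 in bpc. This gene is not among those the label names, and its differences were 0.29 ± 0.16 (adjusted p = 0.51) and 0.72 ± 0.16 (adjusted p = 0.038). BPC7 (AT2G35550; chromosome 2, 14929243 to 14930898) had 0.67 ± 0.246 RPKM in WT with vehicle and 0.65 ± 0.36 with BA, against 0.622 ± 0.258 and 0.521 ± 0.185 in bpc, differences of −0.06 ± 0.28 and −0.14 ± 0.28. Of 7 BPC genes with vehicle, 1 was higher and 4 were lower, or 1 and 4 adjusted over the list alone. BPC genes with vehicle had a median log2 of −0.5 (camera adjusted p = 7.4e-06, and adjusted p = 0.052 with an estimated correlation). Of 7 BPC genes with BA, 1 was higher and 4 were lower, or 2 and 4 adjusted over the list alone. BPC genes with BA had a median log2 of −0.52 (camera adjusted p = 4.6e-07, and adjusted p = 0.033 with an estimated correlation). None of the 7 passed the limma test for a BA response in WT or in bpc.

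The vehicle call of BPC4 was lost at −0.5 with the replicate block (adjusted p = 0.051), no filter, no trend or the 2 groups alone without a block. It was also lost without any single library except WT vehicle 3 and WT BA 1 (−0.6 to −0.42), and its BA call without any BA library or bpc vehicle 2 (−0.58 to −0.48). The call of BPC3 was lost without WT vehicle 1 or 2, bpc vehicle 1 or 2 or bpc BA 1 (0.8 to 1.07), with quantile normalization (0.87) and with the 2 vehicle groups alone (0.95), also with a block. The call of BPC5 was lost without any BA library, WT vehicle 1 or 2 or bpc vehicle 1 (0.62 to 0.82) and with quantile normalization (0.64).

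**Figure D1:**
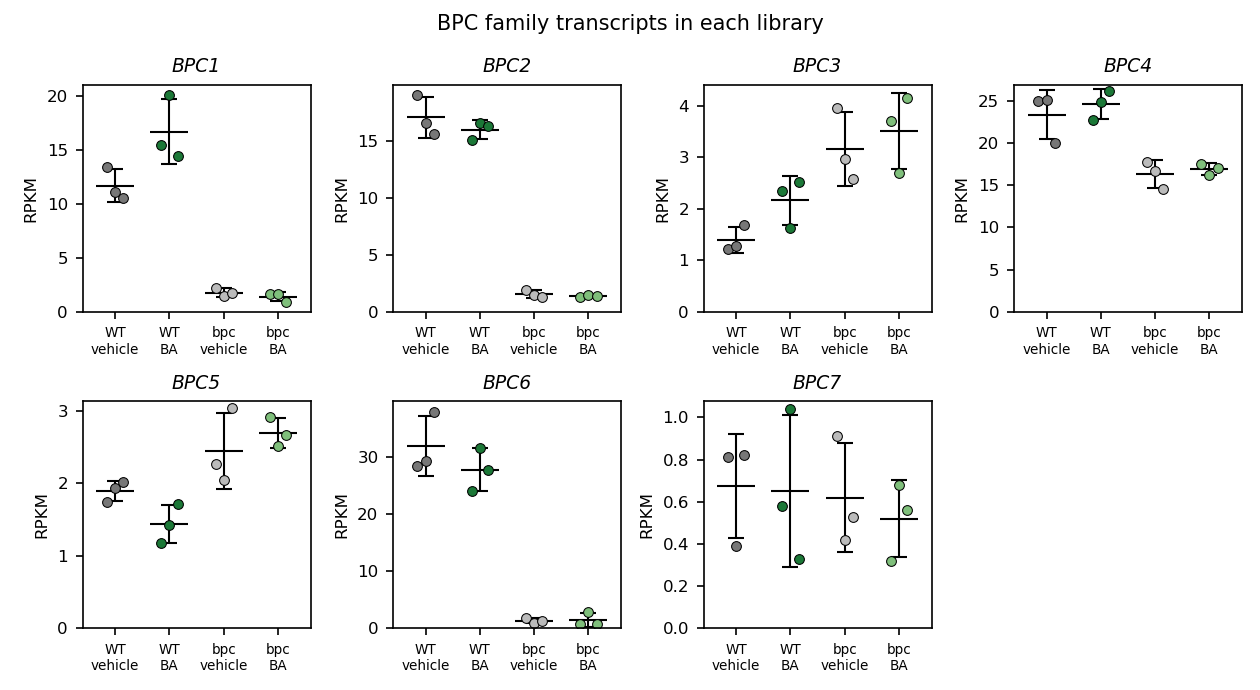
RPKM of the 7 BPC genes in each library (points), by group, with the group mean and SD. BPC1, BPC2 and BPC6 lie lower in all 6 bpc libraries, BPC4 had 16.3 RPKM in bpc against 23.4 in WT with vehicle, and BPC3 had 3.16 against 1.38.

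In WT, BA raised 799 and lowered 1004 of 20776 genes, 390 and 247 of them at least 2-fold. The largest rises were in type-A response regulators, which cytokinin induces. ARR16 (AT2G40670) went from 0.372 ± 0.274 to 33.2 ± 4.2 RPKM (log2 5.31 ± 0.25, adjusted p = 5.7e-08). ARR5 (AT3G48100) went from 5.28 ± 2.58 to 132 ± 25.1 RPKM (log2 4.62 ± 0.28, adjusted p = 4.4e-07). Rises also reached ARR17 (AT3G56380; log2 4.59 ± 0.28, adjusted p = 4.4e-07) and ARR15 (AT1G74890; log2 4.47 ± 0.27, adjusted p = 4.4e-07). Outside this family, AT5G47980 went from 5.97 ± 1.49 to 137 ± 23 RPKM (log2 4.42 ± 0.2, adjusted p = 4.5e-08), with AT1G33740 (log2 4.26 ± 0.28, adjusted p = 8.3e-07) next. The largest fall was in an AP2/ERF gene. ERF53 (AT2G20880) went from 6.87 ± 1.59 to 0.187 ± 0.152 RPKM (log2 −3.42 ± 0.2, adjusted p = 4.4e-07). Further falls were in AT1G27670 (log2 −2.87 ± 0.18, adjusted p = 5.1e-07) and AT3G25011 (log2 −2.43 ± 0.38, adjusted p = 0.0011). The nitrate transporter family member NRT2.6 (AT3G45060) went from 21.8 ± 1.19 to 3.15 ± 1.45 RPKM (log2 −2.7 ± 0.5, adjusted p = 0.0035). The transcription factor genes WRKY54 (AT2G40750; log2 −2.29 ± 0.21, adjusted p = 1.4e-05) and WOX11 (AT3G03660; log2 −2.21 ± 0.32, adjusted p = 0.00066) fell. ARR16 lies on chromosome 2, 16969673 to 16972113, ARR5 on chromosome 3, 17758427 to 17760950, AT5G47980 on chromosome 5, 19428888 to 19430517 and ERF53 on chromosome 2, 8985959 to 8987302.

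Of 10 type-A regulators, 10 rose and 0 fell, or 10 and 0 adjusted over the list alone. Type-A regulators had a median log2 of 3.54 (camera adjusted p = 6.2e-30, and adjusted p = 0.006 with an estimated correlation). Among them were ARR3 (AT1G59940; log2 3.39 ± 0.13, adjusted p = 1.9e-08) and ARR6 (AT5G62920; log2 3.27 ± 0.16, adjusted p = 7.5e-08). Of 9 cytokinin breakdown genes, 6 rose and 0 fell, or 7 and 0 adjusted over the list alone. Cytokinin breakdown genes had a median log2 of 1.58 (camera adjusted p = 3.1e-13, and adjusted p = 0.025 with an estimated correlation). The cytokinin oxidase CKX3 (AT5G56970) went from 0.767 ± 0.146 to 13.3 ± 1.88 RPKM (log2 3.44 ± 0.15, adjusted p = 4.5e-08). Other rises were in the oxidases CKX5 (AT1G75450; log2 2.97 ± 0.18, adjusted p = 4.9e-07) and CKX4 (AT4G29740; log2 2.7 ± 0.21, adjusted p = 3.8e-06) and in the zeatin O-glucosyltransferase UGT85A1 (AT1G22400; log2 1.91 ± 0.13, adjusted p = 8.9e-07). Of 11 CC-type glutaredoxins, 7 rose and 0 fell, or 7 and 0 adjusted over the list alone. CC-type glutaredoxins had a median log2 of 1.8 (camera adjusted p = 1.9e-10, and adjusted p = 0.006 with an estimated correlation). These small redox proteins included GRXS13 (AT1G03850; log2 1.88 ± 0.12, adjusted p = 5.1e-07) and GRXS8 (AT4G15660; log2 3.41 ± 0.26, adjusted p = 3.1e-06), and GRXS6 (AT3G62930; log2 1.48 ± 0.15, adjusted p = 3.6e-05) and GRXS9 (AT2G30540; log2 2.05 ± 0.24, adjusted p = 9.5e-05).

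Of 15 cytokinin biosynthesis genes, 4 rose and 5 fell, or 4 and 6 adjusted over the list alone (median −0.18, camera adjusted p = 0.76). The hydroxylase CYP735A2 (AT1G67110), of trans-zeatin synthesis, went from 10.8 ± 1.77 to 123 ± 12.5 RPKM (log2 3.46 ± 0.13, adjusted p = 1.9e-08). The activating enzyme LOG2 (AT2G35990; log2 3.16 ± 0.22, adjusted p = 1.2e-06) rose too. The isopentenyltransferase IPT5 (AT5G19040) went from 8.4 ± 1.32 to 1.58 ± 0.16 RPKM (log2 −2.09 ± 0.15, adjusted p = 1.6e-06), and IPT7 (AT3G23630; log2 −1.91 ± 0.19, adjusted p = 2.8e-05) fell likewise. Of 14 perception and relay genes, 4 rose and 5 fell, or 5 and 6 adjusted over the list alone (median 0.14, camera adjusted p = 0.64). The receptor AHK4 (AT2G01830) went from 17.9 ± 1.88 to 43 ± 5.65 RPKM (log2 1.24 ± 0.12, adjusted p = 2.3e-05). The phosphotransfer genes AHP3 (AT5G39340; log2 0.71 ± 0.15, adjusted p = 0.0091) and AHP1 (AT3G21510; log2 0.81 ± 0.18, adjusted p = 0.012) rose and the type-B regulator ARR11 (AT1G67710; log2 −0.88 ± 0.17, adjusted p = 0.0058) fell. Of 9 cytokinin response factors, 3 rose and 0 fell, or 4 and 0 adjusted over the list alone (median 0.11, camera adjusted p = 0.15). Those called were CRF5 (AT2G46310; log2 1.09 ± 0.17, adjusted p = 0.0012), CRF6 (AT3G61630; log2 0.77 ± 0.17, adjusted p = 0.0097) and CRF11 (AT3G25890; log2 0.72 ± 0.18, adjusted p = 0.021). AHP1 lost its call without WT vehicle 2 (0.72) or WT BA 3 (0.76). CRF11 lost its call without WT vehicle 2 (0.55) or WT BA 2 or 3 (0.69, 0.68).

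**Figure D2:**
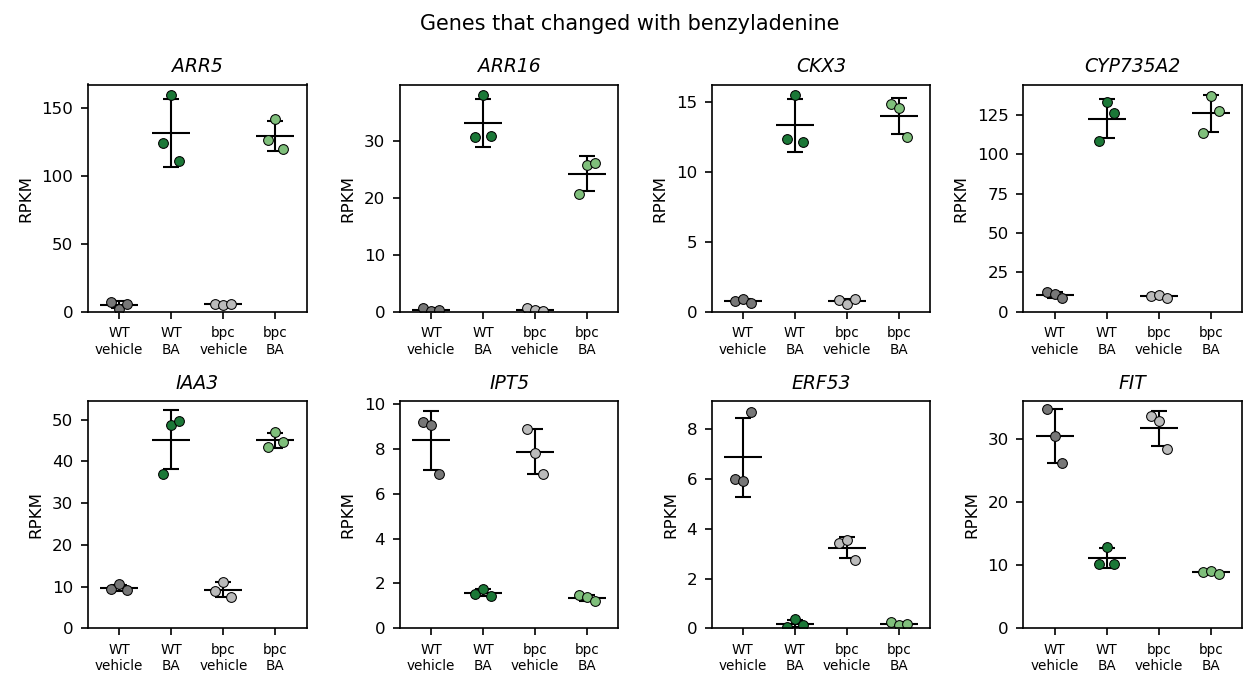
RPKM in each library (points), with the group mean and SD, for ARR5, ARR16, CKX3, CYP735A2, IAA3, IPT5, ERF53 and FIT, chosen for display after their values were seen. The first 5 lie higher and the last 3 lower with BA in both genotypes, for example CKX3 at 0.767 RPKM with vehicle and 13.3 with BA in WT.

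Of 23 Aux/IAA repressors, 6 rose and 1 fell, or 7 and 2 adjusted over the list alone (median 0.1, camera adjusted p = 0.073). IAA3 (AT1G04240) went from 9.71 ± 0.743 to 45.1 ± 7.06 RPKM (log2 2.15 ± 0.14, adjusted p = 9e-07). IAA5 (AT1G15580; log2 1.85 ± 0.19, adjusted p = 3.6e-05) and IAA17 (AT1G04250; log2 0.87 ± 0.15, adjusted p = 0.0021) rose and IAA2 (AT3G23030; log2 −1.42 ± 0.11, adjusted p = 4.6e-06) fell. Of 14 auxin carriers, 1 rose and 3 fell, or 1 and 3 adjusted over the list alone (median −0.14, camera adjusted p = 0.64). The efflux carrier PIN4 (AT2G01420; log2 1.05 ± 0.12, adjusted p = 0.00011) rose, and PIN7 (AT1G23080; log2 −0.48 ± 0.09, adjusted p = 0.0038), PIN3 (AT1G70940; log2 −0.72 ± 0.15, adjusted p = 0.0068) and ABCB1 (AT2G36910; log2 −0.49 ± 0.11, adjusted p = 0.01) fell. Of 19 ethylene genes, 3 rose and 4 fell, or 4 and 9 adjusted over the list alone (median −0.3, camera adjusted p = 0.21). The ACC synthases ACS5 (AT5G65800; log2 2.14 ± 0.19, adjusted p = 1.3e-05) and ACS2 (AT1G01480; log2 0.86 ± 0.13, adjusted p = 0.001) rose, and the receptor ETR2 (AT3G23150; log2 −1.8 ± 0.13, adjusted p = 1.5e-06) and the F-box gene EBF2 (AT5G25350; log2 −1.18 ± 0.15, adjusted p = 0.00022) fell. Of 11 gibberellin genes, 3 rose and 0 fell, or 5 and 1 adjusted over the list alone. Gibberellin genes had a median log2 of 0.27 (camera adjusted p = 0.0026, and adjusted p = 0.35 with an estimated correlation). Those called were GA20ox1 (AT4G25420; log2 2.05 ± 0.18, adjusted p = 1.2e-05), of gibberellin synthesis, and GA2ox2 (AT1G30040; log2 1.19 ± 0.19, adjusted p = 0.0013) and GA2ox1 (AT1G78440; log2 1.37 ± 0.25, adjusted p = 0.0029), which inactivate the hormone. ABCB1 lost its call with the 2 groups alone. The gibberellin metabolism list lost its call with a minimum of 2 RPKM (0.26).

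Of 13 abscisic acid genes, 1 rose and 1 fell, or 1 and 1 adjusted over the list alone (median 0.25, camera adjusted p = 0.6). NCED3 (AT3G14440; log2 1.65 ± 0.17, adjusted p = 3e-05), of its synthesis, rose and the phosphatase ABI1 (AT4G26080; log2 −0.57 ± 0.13, adjusted p = 0.012) fell. Of 20 jasmonate genes, 1 rose and 0 fell, or 1 and 0 adjusted over the list alone (median −0.06, camera adjusted p = 0.68). The rise was in AOC2 (AT3G25770; log2 1.09 ± 0.22, adjusted p = 0.0066), of jasmonate synthesis. Of 11 defence genes, 0 rose and 4 fell, or 1 and 4 adjusted over the list alone (median −0.46, camera adjusted p = 0.054). Those called were PAD4 (AT3G52430; log2 −0.73 ± 0.11, adjusted p = 0.00064), PAD3 (AT3G26830; log2 −0.84 ± 0.16, adjusted p = 0.0047), WRKY53 (AT4G23810; log2 −0.72 ± 0.17, adjusted p = 0.019) and WRKY40 (AT1G80840; log2 −1.35 ± 0.37, adjusted p = 0.038). Of 16 nutrient transporters, 0 rose and 2 fell, or 1 and 7 adjusted over the list alone. Nutrient transporters had a median log2 of −0.42 (camera adjusted p = 0.0052, and adjusted p = 0.77 with an estimated correlation). Beside NRT2.6, the phosphate transporter PHT1;4 (AT2G38940; log2 −1.01 ± 0.13, adjusted p = 0.0003) fell. Of 16 iron-deficiency genes, 0 rose and 2 fell, or 1 and 2 adjusted over the list alone (median 0.07, camera adjusted p = 0.79). The iron regulator FIT (AT2G28160) went from 30.5 ± 4.27 to 11.1 ± 1.58 RPKM (log2 −1.42 ± 0.13, adjusted p = 1.4e-05), and BHLH101 (AT5G04150; log2 −0.89 ± 0.23, adjusted p = 0.029) fell as well. WRKY53 lost its call without WT vehicle 2 (−0.72) or WT BA 1 (−0.52). WRKY40 lost its call without WT vehicle 1, 2 or 3 (−1.42, −1.34, −1.29), WT BA 1, 2 or 3 (−1.35, −1.35, −1.35) or bpc BA 2 (−1.35). BHLH101 lost its call without WT vehicle 1 or 3 (−0.85, −0.85) or WT BA 2 or 3 (−0.95, −0.68). ABI1 and WRKY53 lost their calls with the 2 groups alone. WRKY40 lost its call with no filter, median-of-ratios scaling (−1.3), quantile normalization (−1.3), TPM (−1.32), no trend or WT BA 1 rescaled (−1.29). BHLH101 lost its call with the 2 groups alone or both vehicle libraries numbered 3 left out (−0.85).

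Of 14 hypoxia genes, 1 rose and 5 fell, or 1 and 5 adjusted over the list alone. Hypoxia genes had a median log2 of −0.33 (camera adjusted p = 0.0066, and adjusted p = 0.77 with an estimated correlation). HRE1 (AT1G72360; log2 −1.1 ± 0.12, adjusted p = 6.9e-05), SUS4 (AT3G43190; log2 −0.83 ± 0.16, adjusted p = 0.0054) and PDC2 (AT5G54960; log2 −0.44 ± 0.11, adjusted p = 0.029) fell and HRA1 (AT3G10040; log2 0.84 ± 0.21, adjusted p = 0.026) rose. Of 8 endodermis genes, 0 rose and 2 fell, or 0 and 2 adjusted over the list alone. Endodermis genes had a median log2 of −0.24 (camera adjusted p = 0.02, and adjusted p = 0.65 with an estimated correlation). Those called were SCR (AT3G54220; log2 −0.72 ± 0.14, adjusted p = 0.0056) and the Casparian strip regulator MYB36 (AT5G57620; log2 −0.54 ± 0.14, adjusted p = 0.032). Of 16 root hair genes, 1 rose and 0 fell, or 2 and 2 adjusted over the list alone (median −0.12, camera adjusted p = 0.96). Of 14 xylem genes, 1 rose and 0 fell, or 1 and 0 adjusted over the list alone (median −0.04, camera adjusted p = 0.83). The rises were in RHS18 (AT5G22410; log2 1.45 ± 0.17, adjusted p = 0.00011) and the vessel regulator VND6 (AT5G62380; log2 0.87 ± 0.18, adjusted p = 0.0076). HRA1 lost its call without WT vehicle 1 or 2 (0.62, 0.78) or WT BA 2 or 3 (0.74, 0.86). PDC2 lost its call without WT vehicle 1 or 2 (−0.43, −0.38) or WT BA 1 or 3 (−0.32, −0.47). MYB36 lost its call without WT vehicle 3 (−0.41), WT BA 1 or 3 (−0.48, −0.53) or bpc BA 1, 2 or 3 (−0.54, −0.54, −0.54). Without WT vehicle 2 the nutrient, hypoxia and endodermis lists lost their calls, at medians of −0.36, −0.25 and −0.22. PDC2, HRA1 and MYB36 lost their calls with the 2 groups alone.

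No member passed in 8 further lists. Their median log2, with the camera adjusted p in parentheses, was homeotic floral and KNOX regulators 0.14 (0.74), Polycomb components 0 (0.82), heat-shock proteins −0.34 (0.71) and flavonoid pathway −0.08 (0.96). For the others it was photosynthesis (shoot tissue) −0.16 (0.79), phloem 0.02 (0.92), root cap and stem cell niche −0.07 (0.92) and mitotic cell cycle −0.02 (0.77). Single log2 values were SVP (AT2G22540) 0.25 ± 0.19, SWN (AT4G02020) −0.09 ± 0.12, HSP17.6A (AT5G12030) −0.78 ± 0.31 and F3'H (AT5G07990) −0.21 ± 0.11. Others were LHCB1.2 (AT1G29910) −0.56 ± 0.25, APL (AT1G79430) −0.33 ± 0.11, SHR (AT4G37650) −0.56 ± 0.19 and CDKB1;1 (AT3G54180) 0.36 ± 0.16. Median, mean and test differed in sign for the BPC, jasmonate, Polycomb, iron, root hair, xylem, phloem and mitotic lists. The divisor of WT BA 1 was identical to that of WT vehicle 2. With WT BA 1 rescaled to its own total, 1025 genes rose and 928 fell, and without it 622 fell. Leaving out both vehicle libraries numbered 3 gave 960 and 1202. In the authors' deposited table, 1771 genes were higher and 1939 lower at an FDR under 0.05.

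In bpc, BA raised 880 and lowered 905 genes, 397 and 254 of them at least 2-fold. The type-A regulators again led. ARR16 went from 0.394 ± 0.3 to 24.3 ± 3.05 RPKM (log2 4.83 ± 0.25, adjusted p = 1.3e-07). Next was ARR17 (log2 4.75 ± 0.28, adjusted p = 3.5e-07), and AT5G47980 (log2 4.51 ± 0.2, adjusted p = 4.2e-08) followed. ARR5 went from 5.75 ± 0.439 to 130 ± 11.3 RPKM (log2 4.38 ± 0.28, adjusted p = 6.9e-07). Rises also reached AT4G25410 (log2 4 ± 0.21, adjusted p = 1.6e-07) and ARR15 (log2 3.99 ± 0.27, adjusted p = 1e-06). The largest fall was in GRI. GRI (AT1G53130) went from 12.2 ± 0.583 to 0.949 ± 0.25 RPKM (log2 −3.14 ± 0.19, adjusted p = 5.3e-07). The MYB gene LAF1 (AT4G25560; log2 −2.81 ± 0.22, adjusted p = 3.3e-06) and AT1G27670 (log2 −2.53 ± 0.18, adjusted p = 1.5e-06) fell, as did ERF53 (log2 −2.44 ± 0.2, adjusted p = 7.2e-06) and WRKY54 (log2 −2.42 ± 0.21, adjusted p = 8.4e-06). AT4G12065 had 2.21 ± 0.811 RPKM with vehicle and was listed at 0 in the 3 bpc BA libraries. GRI lies on chromosome 1, 19794723 to 19795544 and AT4G25410 on chromosome 4, 12985661 to 12987521.

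Of 10 type-A regulators in bpc, 10 rose and 0 fell, or 10 and 0 adjusted over the list alone. Type-A regulators in bpc had a median log2 of 3.78 (camera adjusted p = 1.7e-26, and adjusted p = 0.006 with an estimated correlation). ARR3 (log2 3.89 ± 0.13, adjusted p = 5.1e-09) and ARR6 (log2 3.04 ± 0.16, adjusted p = 1.3e-07) were among them. Of 9 breakdown genes in bpc, 6 rose and 0 fell, or 7 and 0 adjusted over the list alone. Breakdown genes in bpc had a median log2 of 1.47 (camera adjusted p = 7.8e-13, and adjusted p = 0.025 with an estimated correlation). CKX3 (log2 3.52 ± 0.15, adjusted p = 4.2e-08) and CKX5 (log2 3.01 ± 0.18, adjusted p = 5.3e-07) rose, with CKX4 (log2 3.1 ± 0.21, adjusted p = 1e-06) and UGT85A1 (log2 2.47 ± 0.13, adjusted p = 1.3e-07). Of 11 glutaredoxins in bpc, 9 rose and 0 fell, or 9 and 0 adjusted over the list alone. Glutaredoxins in bpc had a median log2 of 1.85 (camera adjusted p = 3e-11, and adjusted p = 0.006 with an estimated correlation). They included GRXS13 (log2 1.85 ± 0.12, adjusted p = 6.9e-07) and GRXS8 (log2 3.14 ± 0.26, adjusted p = 6e-06) and GRXS9 (log2 2.64 ± 0.24, adjusted p = 1.2e-05) and GRXS7 (AT4G15670; log2 2.57 ± 0.27, adjusted p = 4.9e-05). In biosynthesis, CYP735A2 (log2 3.62 ± 0.13, adjusted p = 9.4e-09) and LOG2 (log2 3 ± 0.22, adjusted p = 1.9e-06) rose, and IPT5 (log2 −2.17 ± 0.15, adjusted p = 1.2e-06) and IPT7 (log2 −1.89 ± 0.19, adjusted p = 2.9e-05) fell. In perception, AHK4 (log2 1.11 ± 0.12, adjusted p = 5.2e-05), AHP1 (log2 0.88 ± 0.18, adjusted p = 0.0067) and AHP3 (log2 0.64 ± 0.15, adjusted p = 0.018) rose and ARR11 (log2 −1.05 ± 0.17, adjusted p = 0.0018) fell. The response factors CRF5 (log2 0.91 ± 0.17, adjusted p = 0.0044), CRF6 (log2 0.86 ± 0.17, adjusted p = 0.0049) and CRF4 (AT4G27950; log2 0.7 ± 0.14, adjusted p = 0.0056) rose. AHP3 lost its call without bpc vehicle 1 (0.65) or bpc BA 2 or 3 (0.59, 0.66), or with the 2 groups alone.

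Of auxin genes, IAA3 (log2 2.24 ± 0.14, adjusted p = 7.7e-07), IAA17 (log2 1.14 ± 0.15, adjusted p = 0.00027) and IAA5 (log2 1.31 ± 0.19, adjusted p = 0.00062) rose and IAA2 (log2 −1.26 ± 0.11, adjusted p = 1.1e-05) fell. PIN4 (log2 1.01 ± 0.12, adjusted p = 0.00015) and the influx carrier LAX3 (AT1G77690; log2 0.41 ± 0.12, adjusted p = 0.049) rose, PIN7 (log2 −0.54 ± 0.09, adjusted p = 0.0017) and PIN3 (log2 −0.74 ± 0.15, adjusted p = 0.006) fell. For ethylene, ACS5 (log2 2.27 ± 0.19, adjusted p = 7.4e-06) rose, and ETR2 (log2 −1.4 ± 0.13, adjusted p = 1.3e-05), EBF2 (log2 −0.91 ± 0.15, adjusted p = 0.0017) and ERF1 (AT3G23240; log2 −1.68 ± 0.32, adjusted p = 0.0043) fell. Of 11 gibberellin genes in bpc, 4 rose and 0 fell, or 5 and 0 adjusted over the list alone. Gibberellin genes in bpc had a median log2 of 0.36 (camera adjusted p = 0.029, and adjusted p = 0.65 with an estimated correlation). Those called were GA20ox1 (log2 1.89 ± 0.18, adjusted p = 1.9e-05), GA2ox2 (log2 1.57 ± 0.19, adjusted p = 0.00015), GA20ox2 (AT5G51810; log2 0.96 ± 0.22, adjusted p = 0.016) and GA20ox3 (AT5G07200; log2 0.79 ± 0.21, adjusted p = 0.033). NCED3 (log2 1.8 ± 0.17, adjusted p = 1.4e-05) and AOC2 (log2 1.01 ± 0.22, adjusted p = 0.011) rose and ABI1 (log2 −0.54 ± 0.13, adjusted p = 0.016) fell. Of 11 defence genes in bpc, 0 rose and 3 fell, or 0 and 3 adjusted over the list alone. Defence genes in bpc had a median log2 of −0.37 (camera adjusted p = 0.024, and adjusted p = 0.89 with an estimated correlation). Those called were PAD3 (log2 −0.84 ± 0.16, adjusted p = 0.0047), PAD4 (log2 −0.54 ± 0.11, adjusted p = 0.0054) and WRKY40 (log2 −1.43 ± 0.37, adjusted p = 0.028). LAX3 lost its call without any single library except WT vehicle 3 and bpc vehicle 2 (0.29 to 0.44). GA20ox2 lost its call without bpc vehicle 3 (0.92) or bpc BA 2 or 3 (0.89, 0.94). GA20ox3 lost its call without bpc vehicle 1 or 3 (0.63, 0.82) or bpc BA 1, 2 or 3 (0.75, 0.82, 0.82). ABI1 lost its call without bpc vehicle 3 (−0.48) or bpc BA 1 or 2 (−0.51, −0.54). AOC2 lost its call without bpc vehicle 1 (0.82) or bpc BA 3 (0.9). WRKY40 lost its call without bpc BA 1 or 2 (−1.26, −1.43). The gibberellin metabolism list lost its call without WT BA 1 (0.36), bpc vehicle 1 (0.45) or bpc BA 3 (0.38). The defence and immune response list lost its call without bpc BA 1 (−0.24). LAX3 lost its call with no filter, the 2 groups alone, robust empirical Bayes or no trend, and WRKY40 with the first 2. Without both vehicle libraries numbered 3, LAX3 (0.29) and GA20ox3 (0.82) lost theirs. The gibberellin list lost its call with a minimum of 2 RPKM (0.17) and the defence list with array weights (−0.3).

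Of 16 nutrient transporters in bpc, 0 rose and 3 fell, or 1 and 4 adjusted over the list alone. Nutrient transporters in bpc had a median log2 of −0.34 (camera adjusted p = 0.011, and adjusted p = 0.77 with an estimated correlation). Those called were PHT1;4 (log2 −0.91 ± 0.13, adjusted p = 0.00067), the sulfate transporter SULTR2;1 (AT5G10180; log2 −0.54 ± 0.1, adjusted p = 0.0041) and NRT2.6 (log2 −1.98 ± 0.5, adjusted p = 0.024). FIT (log2 −1.77 ± 0.13, adjusted p = 1.9e-06) fell, and the iron genes OPT3 (AT4G16370; log2 0.98 ± 0.16, adjusted p = 0.0017) and F6'H1 (AT3G13610; log2 0.59 ± 0.14, adjusted p = 0.022) rose. HRE1 (log2 −0.97 ± 0.12, adjusted p = 0.0002) fell and HRA1 (log2 0.83 ± 0.21, adjusted p = 0.028) rose. The root hair genes RHS18 (log2 1.27 ± 0.17, adjusted p = 0.00034), RSL4 (AT1G27740; log2 0.65 ± 0.15, adjusted p = 0.018) and RHD6 (AT1G66470; log2 0.62 ± 0.17, adjusted p = 0.044) rose, as did VND6 (log2 0.66 ± 0.18, adjusted p = 0.038). Falls were in SCR (log2 −0.7 ± 0.14, adjusted p = 0.007) and MYB36 (log2 −0.53 ± 0.14, adjusted p = 0.038) and BRN2 (AT4G10350; log2 −0.74 ± 0.19, adjusted p = 0.027) and CYCB2;1 (AT2G17620; log2 −0.67 ± 0.16, adjusted p = 0.018). NRT2.6 lost its call without bpc vehicle 1 or 3 (−1.97, −1.86) or bpc BA 1 or 2 (−1.67, −1.52). F6'H1 lost its call without bpc vehicle 1 or 3 (0.61, 0.44) or bpc BA 2 or 3 (0.56, 0.55). HRA1 lost its call without bpc vehicle 1 or 2 (0.77, 0.74) or bpc BA 1, 2 or 3 (0.82, 0.86, 0.82). RSL4 lost its call without bpc vehicle 1 (0.54) or bpc BA 1 or 2 (0.61, 0.59). RHD6 lost its call without any single library except WT vehicle 2, WT vehicle 3 and bpc vehicle 3 (0.46 to 0.68). VND6 lost its call without WT BA 1 or 2 (0.66, 0.66), bpc vehicle 1 or 2 (0.66, 0.54) or bpc BA 2 or 3 (0.6, 0.56). MYB36 lost its call without WT BA 3 (−0.53), bpc vehicle 2 or 3 (−0.53, −0.41) or bpc BA 1, 2 or 3 (−0.54, −0.54, −0.51). BRN2 lost its call without bpc vehicle 1 or 3 (−0.7, −0.66) or bpc BA 2 (−0.52). CYCB2;1 lost its call without bpc vehicle 3 (−0.56) or bpc BA 2 or 3 (−0.68, −0.62). The nutrient uptake transporters list lost its call without bpc vehicle 2 (−0.21). NRT2.6 and BRN2 lost their calls with the 2 groups alone or both vehicle libraries numbered 3 left out (−1.86, −0.66). HRA1, RHD6, VND6 and MYB36 lost their calls with no filter. So did RHD6 and VND6 with the 2 groups alone, RHD6 and MYB36 with no trend, and RHD6 with TPM.

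Median, mean and test differed in sign for the response factor, abscisic acid, iron, xylem and phloem lists. Without bpc BA 1, 2 or 3, 591, 585 or 569 genes fell. With WT BA 1 rescaled, 968 rose and 1023 fell, and without both vehicle libraries numbered 3, 987 and 998. In the authors' deposited table, 2087 genes were higher and 2612 lower at an FDR under 0.05.

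With vehicle, 189 genes were higher and 225 lower in bpc than in WT, 73 and 96 of them at least 2-fold. The dehydrin RAB18 (AT5G66400) had 1.08 ± 0.921 RPKM in WT and 12.9 ± 2.99 in bpc (log2 3.21 ± 0.45, adjusted p = 0.0031). The late embryogenesis abundant gene LEA7 (AT1G52690) had 1.6 ± 0.74 RPKM in WT and 16 ± 4.78 in bpc (log2 2.99 ± 0.27, adjusted p = 9.7e-05). The malic enzyme NADP-ME1 (AT2G19900) had 1.6 ± 0.329 RPKM in WT and 10.8 ± 0.6 in bpc (log2 2.43 ± 0.15, adjusted p = 3.6e-06). AT2G27402 (log2 2.03 ± 0.22, adjusted p = 0.00036) and the LOB-domain gene LBD26 (AT3G27940; log2 2.34 ± 0.46, adjusted p = 0.02) were higher. MRD1 (AT1G53480) was listed at 0 in WT with vehicle and had 2.15 ± 0.283 RPKM in bpc. The aquaporin PIP3 (AT4G35100) had 337 ± 42.5 RPKM in WT and 37.1 ± 8.34 in bpc (log2 −3.18 ± 0.15, adjusted p = 3.5e-07). The extensin-like AT4G08410 had 52.2 ± 26.7 RPKM in WT and 0.862 ± 1.01 in bpc (log2 −5.41 ± 0.41, adjusted p = 2.5e-05). AT4G12500 (log2 −3.15 ± 0.19, adjusted p = 3.7e-06) and AT1G01725 (log2 −2.48 ± 0.44, adjusted p = 0.012) were lower too. RAB18 lies on chromosome 5, 26518277 to 26519447, LEA7 on chromosome 1, 19619724 to 19621534, NADP-ME1 on chromosome 2, 8591808 to 8595559 and PIP3 on chromosome 4, 16708361 to 16710407. LBD26 lost its call without WT vehicle 1 or 2 (2.25, 1.94) or bpc vehicle 3 (1.97). AT1G01725 lost its call without WT vehicle 1 (−2.18) and, like LBD26, with the 2 groups alone without a block.

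Of 13 abscisic acid genes with vehicle, 4 were higher and 0 were lower, or 8 and 0 adjusted over the list alone. Abscisic acid genes with vehicle had a median log2 of 0.48 (camera adjusted p = 3.3e-07, and adjusted p = 0.13 with an estimated correlation). Beside RAB18, 3 genes inducible by cold or abscisic acid were higher. KIN1 (AT5G15960) had 68.9 ± 17.1 RPKM in WT and 280 ± 42.6 in bpc (log2 2.03 ± 0.2, adjusted p = 0.00018). The others were COR15A (AT2G42540; log2 1.55 ± 0.26, adjusted p = 0.0089) and RD29B (AT5G52300; log2 1.76 ± 0.39, adjusted p = 0.038). Of 7 heat-shock genes with vehicle, 2 were higher and 0 were lower, or 2 and 0 adjusted over the list alone (median 0.28, camera adjusted p = 0.13). The heat-shock factor HSFA2 (AT2G26150) had 2.84 ± 1.06 RPKM in WT and 11.4 ± 1.29 in bpc (log2 1.87 ± 0.25, adjusted p = 0.0018), and the chaperone HSP21 (AT4G27670; log2 1.61 ± 0.22, adjusted p = 0.0021) was higher. Of 5 flavonoid genes with vehicle, 1 was higher and 0 were lower, or 3 and 0 adjusted over the list alone. Flavonoid genes with vehicle had a median log2 of 0.49 (camera adjusted p = 0.0023, and adjusted p = 0.62 with an estimated correlation). The hydroxylase F3'H (log2 0.84 ± 0.11, adjusted p = 0.0019) was the higher gene. Of 14 photosynthesis genes with vehicle, 0 were higher and 0 were lower, or 0 and 3 adjusted over the list alone. Photosynthesis genes with vehicle had a median log2 of −0.34 (camera adjusted p = 0.00018, and adjusted p = 0.77 with an estimated correlation). Values were LHCB1.3 (AT1G29930) −0.75 ± 0.19 and LHCA1 (AT3G54890) −0.67 ± 0.2. In the vehicle libraries numbered 3 this list stood at medians of −0.5 in WT and −0.34 in bpc against the other libraries of the group. RD29B lost its call without any single library except WT BA 1, WT BA 3, bpc vehicle 3 and bpc BA 1 (1.46 to 1.95). The flavonoid pathway list lost its call without WT vehicle 3 (0.39). COR15A lost its call with the 2 groups alone without a block or both vehicle libraries numbered 3 left out (1.36). RD29B lost its call with a pseudocount of 0.1 (2.51), no filter, quantile normalization (1.66) or the 2 groups alone without a block.

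**Figure D3:**
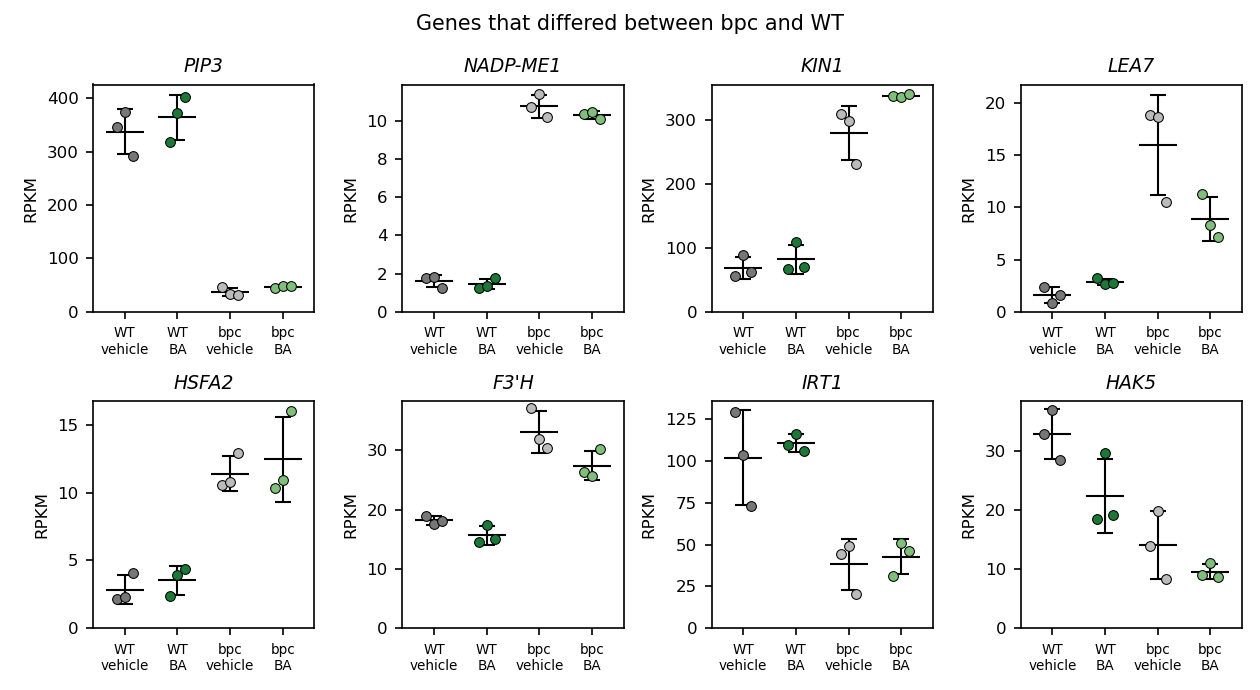
RPKM in each library (points), with the group mean and SD, for PIP3, NADP-ME1, KIN1, LEA7, HSFA2, F3'H, IRT1 and HAK5, chosen for display after their values were seen. With vehicle, PIP3 had 337 RPKM in WT and 37.1 in bpc, and KIN1 had 68.9 and 280.

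Of 20 jasmonate genes with vehicle, 2 were higher and 2 were lower, or 3 and 2 adjusted over the list alone (median 0.16, camera adjusted p = 0.52). The storage protein genes VSP1 (AT5G24780; log2 0.73 ± 0.11, adjusted p = 0.0056) and VSP2 (AT5G24770; log2 0.85 ± 0.15, adjusted p = 0.013) were higher, and LOX3 (AT1G17420; log2 −0.99 ± 0.18, adjusted p = 0.013) and AOC1 (AT3G25760; log2 −1.45 ± 0.32, adjusted p = 0.037), of jasmonate synthesis, were lower. Of 16 iron-deficiency genes with vehicle, 0 were higher and 2 were lower, or 0 and 3 adjusted over the list alone (median 0, camera adjusted p = 0.087). The iron transporter IRT1 (AT4G19690) had 102 ± 28.3 RPKM in WT and 38.1 ± 15.3 in bpc (log2 −1.46 ± 0.3, adjusted p = 0.024), and the ferric reductase FRO2 (AT1G01580; log2 −1.43 ± 0.3, adjusted p = 0.027) was lower. The potassium transporter HAK5 (AT4G13420) had 32.8 ± 4.21 RPKM in WT and 14.1 ± 5.79 in bpc (log2 −1.27 ± 0.26, adjusted p = 0.025). ERF1 (log2 1.62 ± 0.32, adjusted p = 0.02) and GRXS6 (log2 0.78 ± 0.15, adjusted p = 0.02) were higher, as were PCO2 (AT5G39890; log2 0.72 ± 0.15, adjusted p = 0.026) and SVP (log2 0.85 ± 0.19, adjusted p = 0.039). The cellulose synthase CESA7 (AT5G17420; log2 −0.69 ± 0.16, adjusted p = 0.048) was lower. LOX3 lost its call without WT vehicle 2 (−0.94). AOC1 lost its call without any single library except WT vehicle 2, WT BA 2 and bpc vehicle 3 (−1.45 to −1.11). IRT1 lost its call without WT vehicle 1 or 2 (−1.27, −1.43). FRO2 lost its call without WT vehicle 1 or 2 (−1.16, −1.51) or bpc vehicle 1 or 3 (−1.43, −1.14). HAK5 lost its call without WT vehicle 1 or 2 (−1.26, −1.18) or bpc vehicle 1 (−1.31). ERF1 lost its call without WT vehicle 1 (1.47) or bpc vehicle 1 or 3 (1.6, 1.32). GRXS6 lost its call without WT vehicle 1 or 2 (0.79, 0.73) or bpc vehicle 1 or 2 (0.68, 0.79). PCO2 lost its call without WT vehicle 2 or 3 (0.71, 0.61) or bpc vehicle 1 or 2 (0.65, 0.72). SVP lost its call without any single library except WT vehicle 3, WT BA 1 and WT BA 2 (0.68 to 0.96). CESA7 lost its call without any single library except WT vehicle 3 (−0.79 to −0.53). VSP1, VSP2, LOX3, IRT1, HAK5 and GRXS6 lost their calls with the 2 groups alone without a block. So did VSP2 and LOX3 with both vehicle libraries numbered 3 left out (0.67, −0.88). AOC1, FRO2 and SVP lost their calls with no filter or the 2 groups alone without a block. ERF1 lost its call with a pseudocount of 0.1 (1.93), the 2 groups alone without a block or both vehicle libraries numbered 3 left out (1.31). PCO2 lost its call with quantile normalization (0.64), the 2 groups alone without a block or both vehicle libraries numbered 3 left out (0.67). CESA7 lost its call with no filter, the 2 groups alone without a block, no trend or the replicate block (−0.69, adjusted p = 0.056).

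Of 10 type-A regulators with vehicle, 0 were higher and 0 were lower, or 0 and 0 adjusted over the list alone (median 0.06, camera adjusted p = 0.92). Values were ARR8 (AT2G41310) 0.46 ± 0.16 and ARR3 −0.26 ± 0.13, and for other genes PIN4 0.47 ± 0.12, CASP5 (AT5G15290) 0.74 ± 0.19 and WRKY70 (AT3G56400) −0.92 ± 0.3. Median, mean and test differed in sign for the glutaredoxin, Aux/IAA, auxin carrier, ethylene, phloem and root cap lists. With the 2 vehicle groups alone, 26 genes were higher and 54 lower, and with a replicate block added, 390 and 451. With that block, the calls lost with the 2 groups alone passed (adjusted p of 0.006 to 0.047), except BPC3. Without WT vehicle 1 or 2 or bpc vehicle 1 or 2, 71, 102, 106 or 88 genes were higher. Without WT vehicle 1 or bpc vehicle 1 or 2, 103, 129 or 134 were lower. Leaving out both vehicle libraries numbered 3 gave 162 and 196. As deposited, 45.7% of calls were higher, against 35.3% with quantile normalization and 57.4% with array weights. In the authors' deposited table, 1257 genes were higher and 1331 lower at an FDR under 0.05.

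With BA, 268 genes were higher and 213 lower in bpc, 72 and 117 of them at least 2-fold. NADP-ME1 had 1.46 ± 0.281 RPKM in WT and 10.3 ± 0.188 in bpc (log2 2.47 ± 0.15, adjusted p = 2.4e-06). KIN1 had 82.2 ± 23.1 RPKM in WT and 339 ± 2.77 in bpc (log2 2.07 ± 0.2, adjusted p = 0.00015). PIP3 had 364 ± 42.4 RPKM in WT and 47.4 ± 2.38 in bpc (log2 −2.92 ± 0.15, adjusted p = 1e-06). Also higher were RAB18 (log2 2.02 ± 0.45, adjusted p = 0.036) and LBD26 (log2 2.01 ± 0.46, adjusted p = 0.039) and AT5G46295 (log2 2.02 ± 0.4, adjusted p = 0.02) and AT2G27402 (log2 1.95 ± 0.22, adjusted p = 0.00047). AT4G08410 (log2 −5.55 ± 0.41, adjusted p = 1.9e-05) and AT4G12500 (log2 −3.21 ± 0.19, adjusted p = 2.4e-06) were lower. MRD1 was again listed at 0 in WT and had 1.89 ± 0.398 RPKM in bpc. Of 13 abscisic acid genes with BA, 5 were higher and 0 were lower, or 8 and 0 adjusted over the list alone. Abscisic acid genes with BA had a median log2 of 0.68 (camera adjusted p = 3.3e-07, and adjusted p = 0.13 with an estimated correlation). RD29A (AT5G52310; log2 1.2 ± 0.2, adjusted p = 0.0085), the phosphatase HAI1 (AT5G59220; log2 1.27 ± 0.26, adjusted p = 0.024) and COR15A (log2 1.21 ± 0.26, adjusted p = 0.03) were among them. RAB18 lost its call without WT BA 1 or 3 (1.74, 1.97), bpc vehicle 1 (2.02) or bpc BA 1 or 3 (1.57, 2.07). LBD26 lost its call without WT vehicle 1 (2.01), WT BA 1 or 3 (1.66, 1.96) or bpc BA 1, 2 or 3 (1.97, 1.95, 2.12). AT5G46295 lost its call without WT BA 2 or 3 (1.88, 1.88) or bpc BA 1 or 2 (2.06, 1.75). HAI1 lost its call without WT BA 1 or 2 (1.11, 1.29) or bpc BA 1, 2 or 3 (1.24, 1.24, 1.33). COR15A lost its call without WT BA 1, 2 or 3 (1.11, 1.3, 1.23) or bpc BA 1 or 2 (1.1, 1.16). RAB18 and LBD26 lost their calls with a pseudocount of 0.1 (2.23, 2.41) or no filter.

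Of 5 flavonoid genes with BA, 3 were higher and 0 were lower, or 3 and 0 adjusted over the list alone. Flavonoid genes with BA had a median log2 of 0.59 (camera adjusted p = 0.0031, and adjusted p = 0.62 with an estimated correlation). F3'H (log2 0.79 ± 0.11, adjusted p = 0.0025), chalcone isomerase CHI (AT3G55120; log2 0.83 ± 0.16, adjusted p = 0.019) and flavonol synthase FLS1 (AT5G08640; log2 0.59 ± 0.13, adjusted p = 0.033) were higher. HSFA2 (log2 1.69 ± 0.25, adjusted p = 0.0029) and HSP21 (log2 0.93 ± 0.22, adjusted p = 0.044) were higher. Of 14 hypoxia genes with BA, 1 was higher and 0 were lower, or 3 and 0 adjusted over the list alone. Hypoxia genes with BA had a median log2 of 0.28 (camera adjusted p = 0.025, and adjusted p = 0.77 with an estimated correlation). It was the plant cysteine oxidase PCO2 (log2 0.85 ± 0.15, adjusted p = 0.0099). IRT1 had 110 ± 5.21 RPKM in WT and 42.8 ± 10.5 in bpc (log2 −1.39 ± 0.3, adjusted p = 0.029). FRO2 (log2 −1.39 ± 0.3, adjusted p = 0.03) and HAK5 (log2 −1.17 ± 0.26, adjusted p = 0.035) were lower and OPT3 (log2 0.8 ± 0.16, adjusted p = 0.023) higher. CHI lost its call without WT BA 3 (0.72) or bpc BA 1, 2 or 3 (0.84, 0.88, 0.78). FLS1 lost its call without WT BA 1, 2 or 3 (0.6, 0.65, 0.53) or bpc BA 1, 2 or 3 (0.57, 0.62, 0.59). HSP21 lost its call without any single library except WT vehicle 3, WT BA 2, bpc vehicle 2 and bpc vehicle 3 (0.79 to 0.97). PCO2 lost its call without bpc BA 2 or 3 (0.83, 0.82). IRT1 lost its call without WT BA 1, 2 or 3 (−1.4, −1.35, −1.42) or bpc BA 1, 2 or 3 (−1.18, −1.53, −1.46). FRO2 lost its call without WT BA 1, 2 or 3 (−1.43, −1.31, −1.43) or bpc BA 1 or 3 (−1.18, −1.38). HAK5 lost its call without any single library except WT vehicle 2, WT vehicle 3, bpc vehicle 2 and bpc vehicle 3 (−1.28 to −0.95). OPT3 lost its call without WT BA 1, 2 or 3 (0.77, 0.79, 0.84) or bpc BA 1, 2 or 3 (0.83, 0.82, 0.75). The hypoxia response list lost its call without WT BA 2 (0.3) or bpc BA 3 (0.22). The flavonoid pathway list lost its call with no filter (0.1). FLS1 lost its call with median-of-ratios scaling (0.5), quantile normalization (0.53), TPM (0.53) or WT BA 1 rescaled (0.52). HSP21 lost its call with a pseudocount of 0.1 (1.66), a pseudocount of 1 (0.61), the 2 groups alone or the replicate block (0.93, adjusted p = 0.067). IRT1, FRO2 and HAK5 lost their calls with no filter.

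VSP1 (log2 0.63 ± 0.11, adjusted p = 0.013) and VSP2 (log2 0.7 ± 0.15, adjusted p = 0.034) were higher and AOC1 (log2 −1.42 ± 0.32, adjusted p = 0.038) lower. The type-B regulator ARR12 (AT2G25180; log2 −0.81 ± 0.15, adjusted p = 0.014) was lower. LOG8 (AT5G11950; log2 0.57 ± 0.12, adjusted p = 0.026), the floral gene PI (AT5G20240; log2 1.42 ± 0.27, adjusted p = 0.019) and the Casparian strip gene CASP5 (log2 0.79 ± 0.19, adjusted p = 0.048) were higher. Of 16 root hair genes with BA, 0 were higher and 0 were lower, or 3 and 0 adjusted over the list alone. Root hair genes with BA had a median log2 of 0.28 (camera adjusted p = 0.0024, and adjusted p = 0.62 with an estimated correlation). Of 14 photosynthesis genes with BA, 0 were higher and 0 were lower, or 0 and 2 adjusted over the list alone. Photosynthesis genes with BA had a median log2 of −0.14 (camera adjusted p = 0.0066, and adjusted p = 0.96 with an estimated correlation). Of 16 mitotic genes with BA, 0 were higher and 0 were lower, or 0 and 0 adjusted over the list alone. Mitotic genes with BA had a median log2 of −0.1 (camera adjusted p = 0.038, and adjusted p = 0.77 with an estimated correlation). Values were RHS19 (AT5G67400) 0.54 ± 0.14, LHCB1.3 −0.66 ± 0.19 and AUR2 (AT2G25880) −0.28 ± 0.1, and in the type-A list ARR15 −0.55 ± 0.27 and ARR16 −0.45 ± 0.25. VSP1 lost its call without bpc BA 1, 2 or 3 (0.64, 0.64, 0.63). VSP2 lost its call without WT BA 1, 2 or 3 (0.64, 0.71, 0.75) or bpc BA 1 or 2 (0.57, 0.67). AOC1 lost its call without any single library except WT vehicle 2, WT vehicle 3, bpc vehicle 2 and bpc vehicle 3 (−1.55 to −1.27). ARR12 lost its call without WT BA 2 or 3 (−0.78, −0.8) or bpc BA 1, 2 or 3 (−0.85, −0.82, −0.78). LOG8 lost its call without WT BA 1, 2 or 3 (0.54, 0.59, 0.58) or bpc BA 1, 2 or 3 (0.62, 0.54, 0.55). PI lost its call without WT BA 1 or 2 (1.41, 1.38) or bpc BA 1, 2 or 3 (1.52, 1.35, 1.4). CASP5 lost its call without any single library except WT vehicle 3, WT BA 3, bpc vehicle 2 and bpc vehicle 3 (0.66 to 0.86). The photosynthesis (shoot tissue) list lost its call without WT BA 3 (−0.11). The mitotic cell cycle list lost its call without WT BA 1 or 2 (−0.17, −0.05) or bpc BA 2 or 3 (−0.06, −0.06). VSP2 lost its call with median-of-ratios scaling (0.61) or quantile normalization (0.63). AOC1 and the mitotic cell cycle list lost their calls with no filter. CASP5 lost its call with a pseudocount of 1 (0.73), no filter, median-of-ratios scaling (0.7), quantile normalization (0.7), TPM (0.75), no trend or WT BA 1 rescaled (0.72).

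Median, mean and test differed in sign for the perception, biosynthesis, Aux/IAA, auxin carrier, floral, nutrient, endodermis and phloem lists. As deposited, 55.7% of calls were higher. The share was 42.0% (267 against 369) with WT BA 1 rescaled and 34.6% (215 against 406) with median-of-ratios scaling. It was 36.8% (224 against 384) with quantile normalization and 41.1% (251 against 359) as TPM. With the 2 BA groups alone, 538 genes were higher and 357 lower, and without both vehicle libraries numbered 3, 809 and 457. Without WT BA 1, 2 or 3, 90, 169 or 158 genes were higher, and without bpc BA 1, 2 or 3, 71, 69 or 77. Without WT BA 2 or 3, 114 or 109 were lower, and without bpc BA 1, 2 or 3, 101, 109 or 113.

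BA raised 659 and lowered 685 genes in both genotypes, against 33.8 and 43.7 for independent lists, and 1 went opposite ways. Of 458 genes called in WT alone and 440 in bpc alone, 98% and 97.5% had the same direction in the other genotype. The limma interaction test passed for 0 of either, and over all genes for AT3G25221 alone. Unadjusted p was under 0.05 for 338 genes, against 1039 with no change in any gene. The test was thus conservative, and few calls do not show equal responses. Across 20776 genes, which are not independent replicates, the responses correlated at r = 0.82. Deviations shared by vehicle libraries numbered 3 move both responses 1 way and may raise the overlap, shares and r. Interaction values were ARR16 −0.48 ± 0.35, ARR3 0.5 ± 0.19, UGT85A1 0.56 ± 0.18, ETR2 0.4 ± 0.18 and RAB18 −1.19 ± 0.64.

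**Figure D4:**
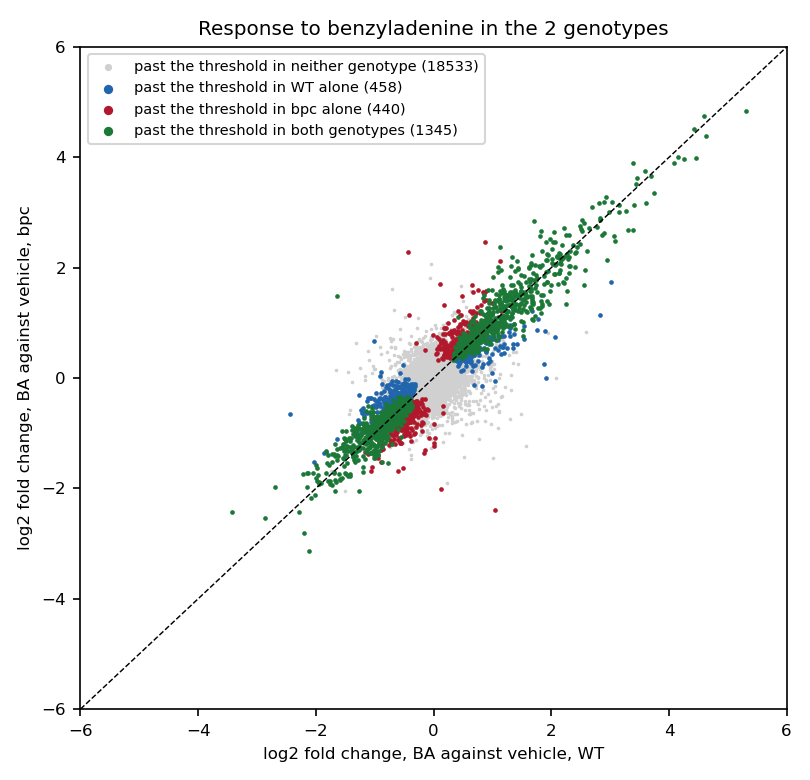
Log2 BA response of each of 20776 genes in WT (x axis) and bpc (y axis), coloured by where limma called it, with a dashed line of equality. 659 genes rose and 685 fell in both, 458 were called in WT alone and 440 in bpc alone.

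The 1387 genes raised by the mean BA effect had median responses of 0.67 in WT and 0.701 in bpc. Their median difference was 0.039, against 0.051 for other genes, with a slope of 0.975. The 1915 lowered genes had medians of −0.58 and −0.55, a difference of 0.039 and a slope of 0.926. Neither set passed camera (p of 0.72 and 0.71). Without WT BA 1 the differences were −0.046 and −0.039. Of 14 hypoxia genes in the interaction, 0 were higher and 0 were lower, or 0 and 0 adjusted over the list alone. Hypoxia genes in the interaction had a median log2 of 0.21 (camera adjusted p = 0.019, and adjusted p = 0.77 with an estimated correlation). Of 16 root hair genes in the interaction, 0 were higher and 0 were lower, or 0 and 0 adjusted over the list alone. Root hair genes in the interaction had a median log2 of 0.26 (camera adjusted p = 0.01, and adjusted p = 0.77 with an estimated correlation). The hypoxia response list lost its call without WT vehicle 2 (0.16), WT BA 2 (0.24), bpc vehicle 1 or 3 (0.2, 0.14) or bpc BA 3 (0.17). The root hair cells list lost its call without WT vehicle 2 (0.16), WT BA 3 (0.21) or bpc vehicle 1 (0.24). The type-A list had a median of −0.15 (camera adjusted p = 0.26). Median, mean and test differed in sign for the biosynthesis, Aux/IAA, auxin carrier, gibberellin, abscisic acid, jasmonate, iron, heat-shock and phloem lists.

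Between the genotype comparisons, 120 genes were higher in both and 144 lower in both, against 2.4 and 2.3 for independent lists, AT3G25221 went opposite ways, and r was 0.68 across genes.

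**Figure D5:**
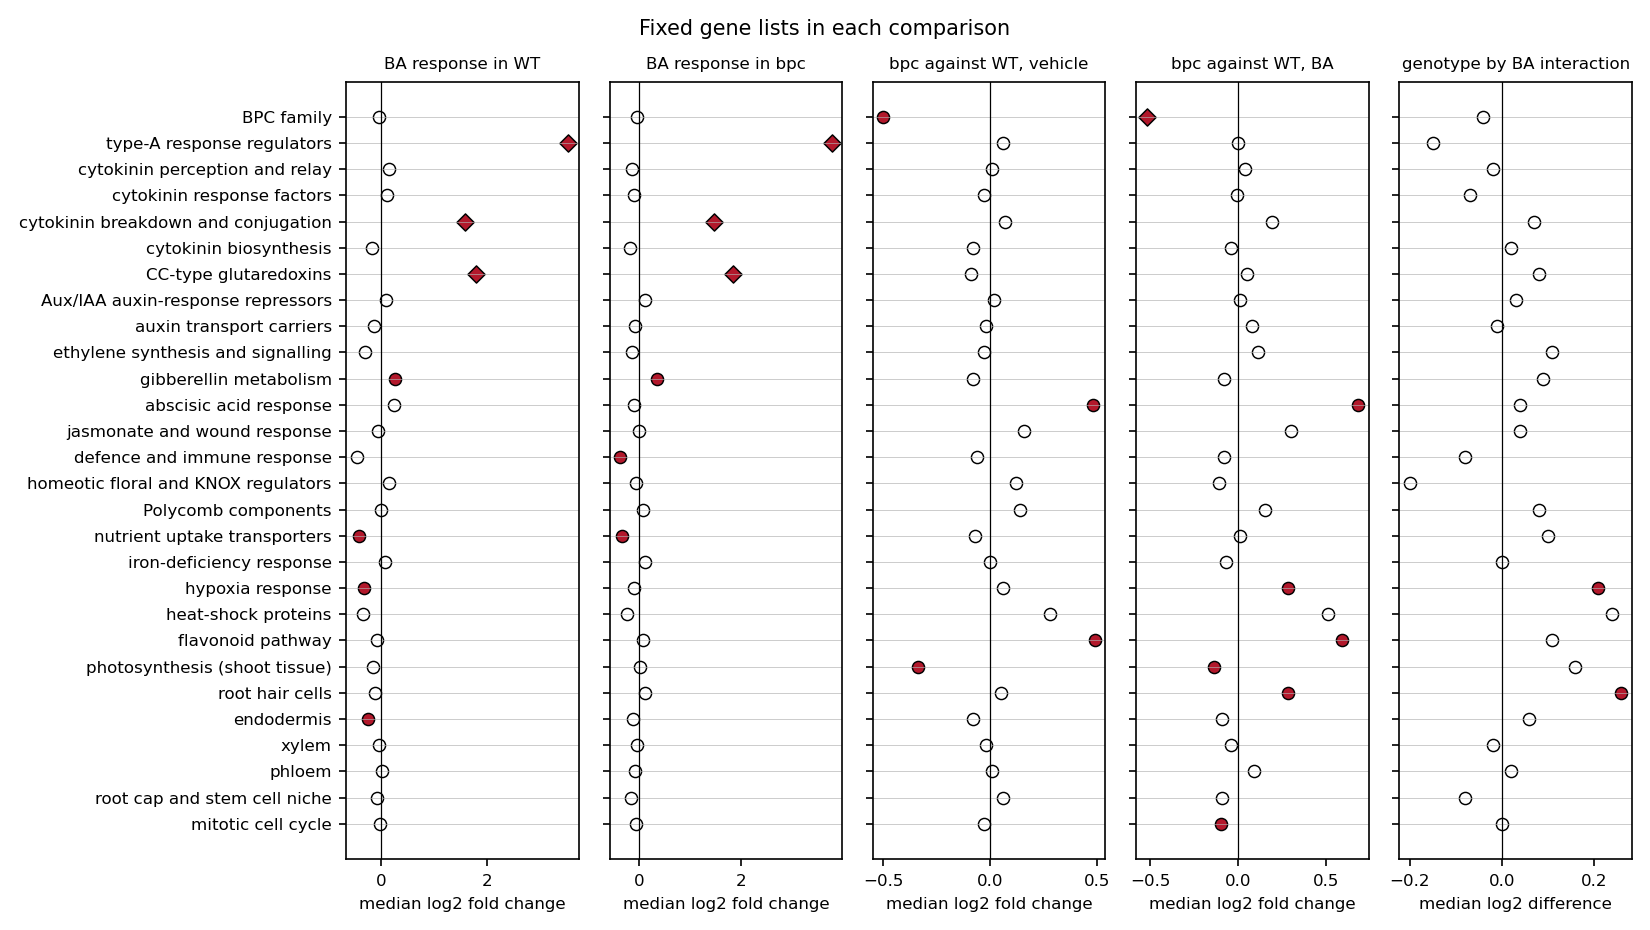
Median log2 fold change of the members of each gene list (points) in the 5 comparisons (panels). Red points passed the camera threshold of 0.05 and diamonds passed it with an estimated correlation as well, as the type-A response regulators did at medians of 3.54 in WT and 3.78 in bpc for BA.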

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

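Among the values here, the choice to describe AT3G25221 was made after its values were seen, because it lies below the level set for named genes.

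The test of the difference between the BA responses of bpc and WT passed for 1 gene. AT3G25221 (chromosome 3, 9184688 to 9184792, 105 bp) had an interaction of 3.11 ± 0.35 (limma adjusted p = 0.02), from a WT response of −1.63 and a bpc response of 1.48. Its 3 WT vehicle libraries held 0.68, 0.82 and 1.89 RPKM, or 1, 1 and 2 reads, and its 3 bpc BA libraries 0.82, 0.87 and 1.01 RPKM, or 1 read each. It was listed at 0 in the WT BA and bpc vehicle libraries. The call was lost without any single library outside WT vehicle, at 3.06 to 3.16, and with a pseudocount of 1 (1.97). When the residuals of a model without the interaction were permuted over the 12 libraries, 6 of 100, the real data included, called at least 1 gene, with up to 8, so chance was not excluded. The test left out the likeness of the vehicle libraries numbered 3 and any pairing of the others.

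The hypoxia list had a median difference between the responses of 0.21 (camera adjusted p = 0.019, and adjusted p = 0.77 with an estimated correlation). The root hair list had 0.26 (camera adjusted p = 0.01, and adjusted p = 0.77 with an estimated correlation). Neither passed with fry, and the libraries on which each call rests are named with the comparison.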

How the results depend on the processing

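Of the alternatives below, rescaling WT BA 1, leaving out both vehicle libraries numbered 3, and fitting the 2 vehicle groups alone with a block were chosen only after the data were seen. Of 205 calls of named genes, 138 held in every alternative tried and 67 were lost in at least 1, 62 of these when a library was left out. Over all alternatives, 5540 of 5993 values of named genes kept their direction and side of the threshold, 417 lost the call and 36, all of uncalled values in the BPC family, changed sign. Of 702 list values, 645 kept the call and 57 lost it. Depth limits 1 kb genes under about 1 RPKM, and shorter ones above it, to few reads. The cause of the changes below was not tested, but leaving out libraries or groups leaves fewer samples.

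The interaction called 0 genes higher with a pseudocount of 1 or a minimum of 2 RPKM, and 1 gene lower with a pseudocount of 0.1, without an intensity trend or with array weights. Without a filter it called 2 higher and 2 lower. BPC4 with vehicle lost its call at −0.5 without a filter, without a trend, with 2 groups alone and with the replicate block. With median-of-ratios scaling, 347 genes were lower with vehicle and 406 with BA, the differences in response size turned to −0.012 and −0.01, and 4 lists passed the interaction. Quantile normalization gave 350, 384, −0.001, −0.013 and 4, and BPC3 with vehicle (0.87) and BPC5 with BA (0.64) lost their calls. TPM gave 359 lower with BA, −0.021 for both differences and 4 lists. With WT BA 1 rescaled the values were 369, −0.025, −0.027 and 4.

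With 2 groups alone, 26 and 54 genes passed with vehicle and 538 and 357 with BA, and BPC3 lost its call at 0.95. Adding the replicate block to the 2 vehicle groups gave 390 and 451, with BPC3 again at 0.95 without a call. In the fit of 4 groups, the replicate block ended the calls of BPC4 with vehicle, CESA7 with vehicle and HSP21 with BA, and of no other named gene. Array weights gave 1726 and 1964 genes for BA in bpc, 1017 and 755 with vehicle, 840 and 678 with BA, and 1010 genes higher in both responses. They turned the BA response in bpc of BPC3 (−0.05) and BPC4 (−0.04), BPC7 with vehicle (0.1) and the interaction of BPC6 (−0.15), none of them called. Without both vehicle libraries numbered 3, 809 and 457 genes passed with BA, and 2 genes higher and 5 lists in the interaction. Uncalled values then turned for BPC4 (−0.03 in WT and −0.03 in bpc for BA, 0 for the interaction) and BPC7 (0.05 for BA in WT, 0.08 with vehicle).

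With an estimated correlation camera called 3, 3, 0, 1 and 0 lists in the 5 contrasts, and fry called 4 between genotypes with BA and 0 in the interaction. The calls of the nutrient lists for BA, the defence list for BA in bpc, the photosynthesis lists between genotypes, and the hypoxia and mitotic lists with BA were lost with fry. Choosing the genes by their call in WT gave differences in response size of −0.025 and 0.101, and by their call in bpc 0.091 and −0.025, which by construction favours the genotype used to choose.

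With each library left out in turn, BA in WT gave 591 to 905 genes higher and 622 to 1177 lower, and BA in bpc 608 to 999 and 569 to 1056. With vehicle, 71 to 204 were higher and 103 to 231 lower, and with BA 69 to 365 and 101 to 265; the libraries behind these are named in the comparisons. The interaction called 0 to 1 genes. Lists called ranged over 4 to 9 for BA in WT (4 without WT vehicle 2), 4 to 7 with vehicle (7 without bpc vehicle 2) and 0 to 4 in the interaction (4 without WT vehicle 1, 0 without bpc vehicle 1, 1 without WT vehicle 2, WT BA 2, WT BA 3 or bpc BA 3). The differences in response size ranged over −0.046 to 0.085 and −0.039 to 0.097. They were lowest without WT BA 1, and passed the test without WT vehicle 1 (0.002) for genes raised and without bpc vehicle 1 (0) or bpc vehicle 2 (0.01) for genes lowered.

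Calls within the BPC family ranged over 0.8 to 1.07 (BPC3 with vehicle), −0.6 to −0.42 and −0.58 to −0.48 (BPC4 with vehicle and BA) and 0.62 to 0.82 (BPC5 with BA). Uncalled values that changed sign ranged, for BA in WT, over −0.03 to 0.13 (BPC4) and −0.28 to 0.16 (BPC7). For BA in bpc they ranged over −0.03 to 0.12 (BPC4), −0.49 to 0.23 (BPC6) and −0.26 to 0.05 (BPC7). BPC7 ranged over −0.25 to 0.07 with vehicle and −0.35 to 0.09 with BA. In the interaction the ranges were −0.14 to 0.07 (BPC2), −0.1 to 0.08 (BPC4), −0.3 to 0.42 (BPC6) and −0.29 to 0.15 (BPC7).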

Other observations

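The families below, the tests of WT BA 1 and, for the vehicle libraries numbered 3, those of few genes and shoot tissue were chosen only after the result was seen.

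Genes whose symbols share a stem were tested as families, 192 of them in 960 camera tests, of which 9 passed and 0 passed with an estimated correlation. Of 24 genes of the ERF stem, mostly ethylene response factors, 8 fell with BA in WT (median −0.46, camera adjusted p = 0.00058) and 9 in bpc (−0.58, 0.00044; adjusted p = 1 for both with an estimated correlation). ERF2 (AT5G47220) fell from 12.5 ± 1.81 to 2.41 ± 0.348 RPKM in WT. Of 9 SADHU genes, which are SINE-like retroposons, 4 were lower in bpc with vehicle (median −0.69, camera adjusted p = 0.00015) and 3 with BA (−0.4, 5.7e-05; adjusted p = 0.99 for both with an estimated correlation). SADHU10-1 (AT3G58865) had 8.18 ± 1.85 RPKM in WT with vehicle and 1.29 ± 0.553 in bpc (log2 −2.31 ± 0.21, limma adjusted p = 9.7e-05). The RR stem passed as well for BA (median 0.64 in WT and 0.21 in bpc, adjusted p = 1 for both with an estimated correlation), with 9 response regulators that the fixed cytokinin lists also hold. RPL genes had a median of −0.17 with vehicle (camera adjusted p = 0.034, and adjusted p = 1 with an estimated correlation), lost with quantile normalization (−0.13), array weights (−0.12) or without vehicle library 2 or 3 of either genotype (−0.19 to −0.14).

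The counts of called genes were compared with other splits of the libraries. For BA in WT, 1803 genes were called against at most 1 in another split, for BA in bpc 1785 against 1, with vehicle 414 against 9, and with BA 481 against 1. Each of these designs has 10 splits, too few for a share under 0.05. The other vehicle splits that part all 3 numbered pairs, as the real one does, called 0 genes, and the split that called 9 kept pairs 1 and 3 together. For the mean BA effect, 1 of 100 reassignments, the real one, gave as many as 3302, the highest other calling 1. This argues against a chance split if libraries are independent, which the labels do not show. The test left out shared growth or handling of a group and the pairing of the vehicle libraries.

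WT BA 1 had a length-weighted RPKM sum of 86.5% of the median. Its divisor equals that of WT vehicle 2 to the read, which is consistent with its counts having been divided by the read total of that library. A few genes taking most of the reads is argued against, since its 10 highest genes held 3.81% of the RPKM, against 3.73% to 7.55% in the other libraries. No biological explanation was tested.

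The vehicle libraries numbered 3 deviated alike in WT and bpc, with 120 genes at least 2-fold higher and 107 lower in both, against 8 and 12 for the BA libraries numbered 3. The 10 highest genes held 6.36% and 7.55% of the RPKM there, against 3.73% to 4.34% elsewhere, among them the extensin EXT3 (AT1G21310) with 17672.3 and 22184.8 RPKM, against 6344.7 to 8571.4 in the other vehicle libraries. Such genes would move the others 1 way, but without them and after median-of-ratios scaling 125 genes were higher and 104 lower, and the correlation of the deviations was 0.64 after removing trends on length and GC content, which argues against both as the whole cause. A lower share of shoot tissue could account for the nuclear photosynthesis list (medians −0.5 and −0.34, with −0.32 to 0.36 in other libraries), but plastid-encoded genes went the other way (0.86 and 0.61, with −0.68 to 0.48 elsewhere). Capture of plastid RNA by poly(A) selection may vary, so shoot tissue stays open for the nuclear genes, and no biological explanation was tested.

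Genes called between bpc and WT with vehicle might lie in chromosome segments carried with the insertions. Within 1 Mb of the 5 genes lay 31 of 407 called genes (7.62%) and 1842 of 20181 others (9.13%), a ratio of 0.834 (95% interval 0.593 to 1.17), which argues against such segments for the set. GA repeats (GAGAGAGA or TCTCTCTC within 1 kb upstream) were in 20 of 186 higher genes and 39 of 221 lower genes, against 2956 of 20183 others. The ratios were 0.734 (0.485 to 1.11) and 1.2 (0.905 to 1.61), with Fisher's exact adjusted p = 0.21 for both. The intervals leave a role of the repeats open in either set, and loss of the BPC proteins stays open, untested.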
